A study of Mus musculus with 12 samples.

How the data were processed

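The samples are 12 pools of total RNA from mouse olfactory epithelium, 4 male mice per pool, taken every 4 h from CT12 to CT56 in constant darkness. Per the labels' protocols, RNA was extracted with Trizol, amplified with a random-primed whole-transcript kit, labelled with biotin and hybridised to Affymetrix arrays. The deposited values comprise 1 number per probe and pool. Per the submitters' processing notes the tool affy was used, with no version or role. The background correction, normalization and centring are not given in the sources used here. The deposited values were read as log2 intensities from their range, since they span about 3.5 to 14.5, above the natural log of the largest 16-bit scanner value, 11.09, and below its log2 of 16. The medians of the 12 columns lie between 7.81 and 7.92. The deposited log2 values were used as they stand, with no floor and no filter on dim probes in the main fit.

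Of 34760 probes, the platform annotation lists 22961. Of these, 21640 have 1 gene symbol and 1321 have several, and 11799 probes are not listed and are unnamed here. Probes with 1 symbol were looked up by Entrez ID in a RefSeq gene table of the assembly GRCm38.p6, used for names only. There were 21553 matches, and 0 symbols changed. A gene with more than 1 probe, as 954 had, was represented by the probe with the highest mean over all pools, which left 19937 genes. No genome was used, and no coordinates are given. The 13120 probes without 1 symbol were fitted separately, and 0 of them passed (325 at an unadjusted p under 0.05).

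Rhythms were fitted with limma 3.58.1 in R 4.3.3 (data handling with version 1.17.8 of the data.table package) as a cosine and a sine of 24 h over all 12 pools, with 9 residual degrees of freedom, a moderated F test and Benjamini-Hochberg adjustment over all genes. The amplitude is the distance from the mean to the peak on the log2 scale, with a standard error from the fit. Subjective night (phases 12, 16 and 20 h) was compared with subjective day (0, 4 and 8 h) as 2 groups. The cycles were compared with phase as a factor. A 12 h cosine was tested beside the 24 h terms, and a change of rhythm as the interaction of the 24 h terms with cycle. The threshold was an adjusted p of 0.05. Gene lists, 39 in all with 1724 measured genes, were tested by the 24 h fit of the list mean against 100000 random orders of the pools, by Fisher's exact test (one-sided) and by camera with a preset correlation of 0.01 and with an estimated one. By Fisher's test the 5 rhythmic genes were enriched in the clock loop, which held 2 of them (adjusted p = 0.000108). They were also enriched in the clock output factors, on 1 gene, Dbp (adjusted p = 0.0342). The other 37 lists held 0 of the 5 genes, so the test could not call them. The difference of a list between cycles was tested with an exact sign-flip test over 6 pairs of pools, two-sided. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and Python 3.11.15.

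The rule for named genes was set before the data were examined. It names all measured genes of the clock loop and the output factors. It adds up to 10 genes by amplitude among those past the threshold with a peak in the day and up to 10 in the night, leaving out receptors, predicted genes and the clock genes. For each other list it names up to 4 members past the threshold, or else the member with the smallest p. For the contrasts between groups it names up to 6 genes per direction past the threshold, and for the 12 h and interaction tests up to 5. Genes outside this rule are marked as named after their values were seen, or carry the smallest p of a test with no call. Those outside it in the part on flagged results, such as Obp1a, Xist and the other sex-linked genes, were also named after their values were seen. The alternatives were quantile normalization, median centring, leaving out the genes below the 25th percentile of the mean level or those below the 50th, the mean of all probes, a trended robust variance prior, array weights, a linear term of time, a block for cycle, periods of 22 and 26 h, phase as a factor, 12 h terms, a rank test with 1000000 permutations, other forms of the contrasts and leaving out each pool. After the data had been seen, the first residual component as a covariate and leaving out CT32 and CT56 together were added. The group of small nucleolar RNA genes, taken by symbol, and the list means without each pool or pair of pools were also added then.

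The fits were tested on simulated data with the means and residual spreads of the 19937 genes, in which 200 genes were changed. For the 24 h fit, 62.7% of genes with an amplitude of 0.3, 92.5% at 0.5 and 100% at 1 were found, with 11 false calls. For night against day the shares were 44.8%, 80.6% and 100% for differences of 0.3, 0.5 and 1, and for the second against the first cycle 23.9%, 68.7% and 100%. The simulated genes were independent, unlike genes that share variation between pools.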

Results

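The data describe the olfactory epithelium of the mouse, the sheet of sensory neurons, supporting cells, basal cells and glands that lines the back of the nasal cavity. Tissue of male C57BL/6 mice was taken every 4 h over 2 circadian cycles in constant darkness, after the animals had been held in a light and dark cycle. Each of the 12 time points, from CT12 to CT56, was a single pool of RNA from 4 mice, 48 mice in all, hybridised to 1 array. Circadian time (CT) 0 to 12 is the subjective day, the rest phase of a mouse, and CT 12 to 24 the subjective night. The 12 pools fall into 6 phases of the day with 2 pools each, which lie 24 h apart. The p-values therefore measure the spread between pools, not between single mice, and the number of arrays limits the precision. Pearson correlations between pools over all probes lay between 0.964 and 0.995, a measure that differences in level between probes keep high. The CT56 pool stood apart, with a mean correlation of 0.975 with the others, against 0.981 for the next lowest, CT32. CT56 and CT52 also had the lowest array weights, 0.33 and 0.47. The first principal component of the gene values held 40.1% of the variance, with CT56 at 26.6 and CT36 at -23.8 as its ends. Pools of the same phase had a mean correlation of 0.9866 against 0.9847 for the other pairs (permutation test, one-sided, p = 0.189).

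The first question was which transcripts follow a 24 h rhythm. Genes of the circadian clock led the list. Dbp, a transcription factor driven directly by the clock, had an amplitude of 0.51 ± 0.05 (SE, 12 pools) on the log2 scale, with a fitted peak at CT 7.8 and a peak level 2.02-fold above the trough (limma, adjusted p = 0.00173). Its pools read 9.80 and 9.91 at CT32 and CT56, and 8.98 and 8.85 at CT20 and CT44. Nr1d1, a repressor within the clock loop, peaked at CT 6.0 with an amplitude of 0.42 ± 0.04 (limma, adjusted p = 0.00173). Arntl, which encodes the activator BMAL1, peaked at CT 21.6 with an amplitude of 0.35 ± 0.04 (limma, adjusted p = 0.0141), so that its maximum fell in the late subjective night while Nr1d1 stood near its lowest value. Outside the clock, Cd44, a cell surface receptor for hyaluronan, rose and fell with an amplitude of 0.56 ± 0.06 and a peak at CT 21.8 (limma, adjusted p = 0.00285). Rnase1, a secreted ribonuclease, peaked at CT 9.0 with an amplitude of 0.42 ± 0.05 (limma, adjusted p = 0.0236). These 5 genes were the ones of 19937 that passed an adjusted p of 0.05 in the limma fit. At an unadjusted p under 0.05 there were 706 genes, where chance alone would give 997, and a rank test called 0 after adjustment and 723 before it. That 0 says nothing on the 5 limma calls. With 12 pools, the smallest p of the rank test is too large for 5 genes alone to pass over 19937. The limma count of 706 rested on single pools, since it was 1221 without the pool at CT52 and 1141 without that at CT56. It was 1424 with array weights and, in fits added after the data were seen, 2143 without CT32 and CT56 together and 2514 with a residual component as a covariate. That component was taken from the residuals of this same fit. It leaves each cosine as it was and removes the largest shared part of the residual spread, so it favoured a higher count from the start. Without the pool at CT20, CT24, CT36, CT44 or CT48, Arntl lost its call, with an adjusted p of at most 0.0731 in limma, and Rnase1 kept its call without CT28, CT40 or CT52 only. With cycle as a block Rnase1 also lost its call (limma, adjusted p = 0.0575).

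**Figure D1:**
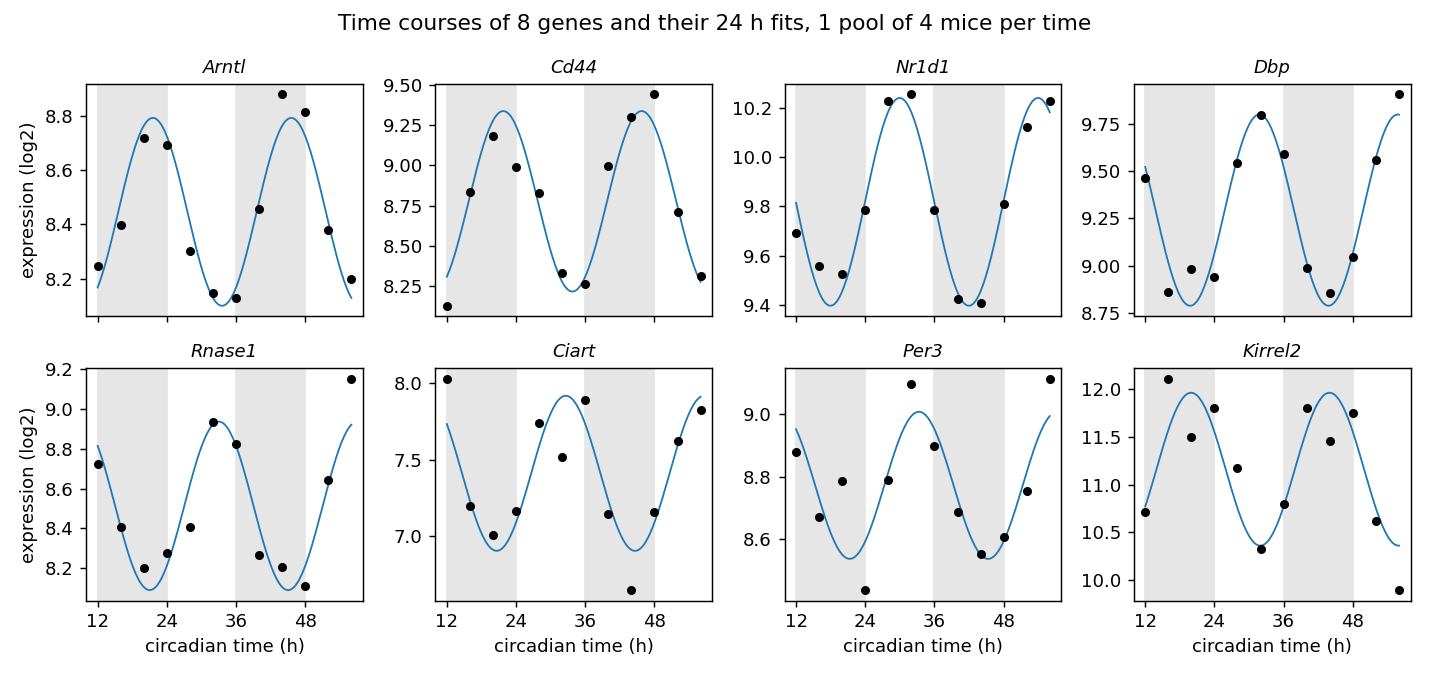
Expression (log2, vertical axis) against circadian time in h (horizontal axis) for 8 genes. Points are the 12 pools of 4 mice, lines the fitted 24 h cosine and grey bands the subjective night. Arntl and Cd44 rise towards CT20 to CT24 in both cycles, while Nr1d1, Dbp and Rnase1 peak between CT 6.0 and CT 9.0.

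Among the genes of the clock loop and its output factors, 18 of the 20 in the lists were measured. Of these, 3 passed over all genes, and 9 had an unadjusted p under 0.05. In the loop itself, 2 of 11 members passed over all genes and 3 when adjusted over the list alone, the third being Per3 (amplitude 0.24 ± 0.05, peak at CT 9.3). Among the output factors, 1 of 7 passed over all genes and 4 when adjusted over the list alone. These were Dbp, Ciart, Hlf and Bhlhe41. Without the pool at CT16, or without that at CT32, 2 of the 7 passed over the list alone, as they did without CT32 and CT56 together. Ciart, a repressor of the loop, had an amplitude of 0.51 ± 0.07 and a peak at CT 8.6, with an adjusted p of 0.104 over all genes in limma. Hlf, a relative of Dbp, had an amplitude of 0.16 ± 0.04 with a peak at CT 7.0, and Bhlhe41 one of 0.22 ± 0.07 with a peak at CT 6.1. Per2, with an amplitude of 0.12 ± 0.04, and Per1, with one of 0.15 ± 0.06, did not pass over the list alone, nor did Tef, with one of 0.13 ± 0.05 and a peak at CT 9.7, and Bhlhe40, with one of 0.16 ± 0.05 and a peak at CT 4.6 (limma, adjusted p over the list alone 0.0585 and 0.0507). Nfil3 had an amplitude of 0.02 ± 0.05 and Nr1d2 one of 0.07 ± 0.04, with Clock, Cry1, Cry2 and Rora between them, and Rorb one of 0.13 ± 0.05. The mean of the output factors followed the 24 h cosine with an amplitude of 0.22 ± 0.02 and a peak at CT 7.7 (permutation test of the pool order, p = 4e-05, adjusted p = 0.00156 over 39 lists). That mean is not scaled per gene, so Dbp and Ciart, with the largest amplitudes, weigh most in it. Members of the loop peak at different times, and their mean had an amplitude of 0.03 ± 0.02 (permutation test, adjusted p = 0.828).

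**Figure D2:**
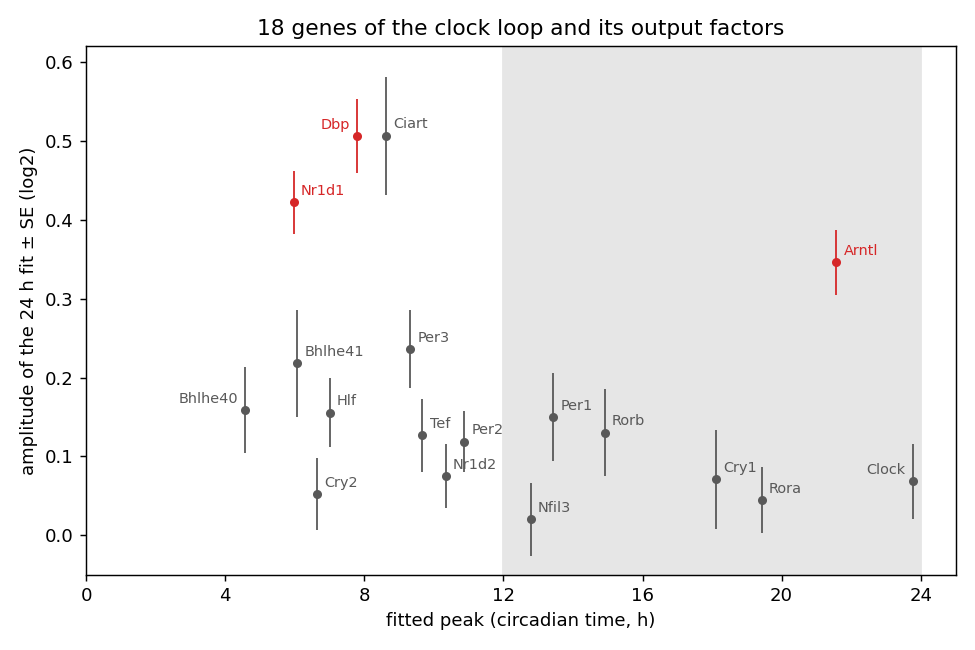
Amplitude of the 24 h fit (log2, vertical axis, bars are the SE) against the fitted peak in circadian time (h, horizontal axis) for 18 genes of the clock loop and its output factors. Red points passed an adjusted p of 0.05 over all genes, and the grey band is the subjective night. Arntl peaks at CT 21.6, and Nr1d1, Dbp, Ciart and Per3 between CT 6.0 and CT 9.3.

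The other 38 lists, fixed before the data were examined, covered odour detection, cell types of the epithelium and its neighbours, and metabolic and stress pathways. Their list means had 24 h amplitudes between 0.01 and 0.23, and their adjusted p lay between 0.828 and 0.952 in the permutation test. Of the 22 measured genes of odorant transduction, the step from receptor to current, 0 passed in limma and 1 had an unadjusted p under 0.05, the chloride importer Slc12a2 (amplitude 0.11 ± 0.04, peak at CT 20.5). Of 1015 odorant receptor genes, 0 passed in limma and 34 had an unadjusted p under 0.05. The receptor with the smallest p was Olfr591, with an amplitude of 0.33 ± 0.07, a peak at CT 5.4 and an adjusted p of 0.518 in limma. Probes for such receptors can also bind related family members. Of 13 trace amine receptors, 0 had an unadjusted p under 0.05, and of 165 vomeronasal receptors 7 did. A member passed when adjusted over the list alone in 6 lists, which included both clock lists. In the axon guidance list these were 3 of 11 genes. Kirrel2, an adhesion molecule of sensory axons that also belongs to the mature neuron list, had an amplitude of 0.80 ± 0.13 and a peak at CT 19.9. The pair Epha5 and Kirrel3, named after their values were seen, had amplitudes of 0.39 ± 0.09 and 0.21 ± 0.05 with peaks at CT 20.7 and CT 11.6. Usp2, a deubiquitinase held by 2 of the clock-related lists, had an amplitude of 0.20 ± 0.05 and a peak at CT 11.1. Over all genes the adjusted p in limma was 0.142 for Kirrel2, 0.857 for Epha5, 0.946 for Kirrel3 and 0.857 for Usp2. Adjusted over the list alone, 0 axon guidance genes passed in the rank test, and 2 passed with median centring, with a period of 26 h or without the pool at CT12.

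The next question was where in the day the peaks lie. Of the 5 rhythmic genes, 3 peaked in the subjective day and 2 in the subjective night. Both night genes, Arntl and Cd44, had peaks between CT 20 and CT 24. Of the 185 genes with an unadjusted p under 0.01, a number that is not a count of calls, 131 had peaks in the subjective day and 54 in the night, and 87 lay between CT 4 and CT 8. No test was made of this unevenness, since genes are not independent replicates.

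Subjective night was then set against subjective day, 6 pools against 6. No gene passed in limma, and 1965 had an unadjusted p under 0.05, of which 831 were higher and 1134 lower at night. The smallest p belonged to Mpped2, which read 0.38 log2 lower at night (night minus day -0.38, adjusted p = 0.497 in limma). Among the lists, camera with a preset correlation called 10 and with an estimated correlation 0. The 78 measured genes of oxidative phosphorylation read lower at night in 66 cases, with a list mean difference of -0.07 (adjusted p = 0.675 with an estimated correlation), which was -0.045 without the pool at CT56. Motile cilia genes, which mark respiratory cells at the edge of the tissue, read lower in 14 of 18 cases, with a mean of -0.16 (adjusted p = 0.675 with an estimated correlation). Vomeronasal receptors read higher in 127 of 165 cases, by a mean of 0.06 (adjusted p = 0.675 with an estimated correlation). Their list mean was 0.09 at CT36, -0.10 at CT24 and -0.05 at CT48. The 25th percentile of all probes in these pools was 6.71, 6.59 and 6.57, so the list was high where dim probes read high. Scaling that depends on level was not tested for this or the other lists. Heat shock genes, which encode protein chaperones, read lower in 14 of 16 cases by a mean of -0.08, and glucocorticoid targets higher in 11 of 15 by 0.07. Their adjusted p were 0.711 and 0.675 with an estimated correlation. The clock output factors had a mean of -0.18, and the lists of muscle, brain, bone and lymphocyte genes means of 0.15, 0.12, 0.17 and 0.09, the last being 0.058 without the pool at CT48. With an estimated correlation the adjusted p over the 39 lists lay between 0.675 and 0.953.

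The second cycle was compared with the first, phase by phase, which asks whether levels drift in constant darkness. The labels do not say whether the arrays were run in batches. Time in darkness therefore cannot be told apart from a batch that runs along with the cycle. No gene passed in limma, and 2625 had an unadjusted p under 0.05, of which 842 were higher and 1783 lower in the second cycle. The gene with the smallest p was Omd, an extracellular matrix protein of bone, at 0.53 ± 0.06 higher (limma, adjusted p = 0.0723). Genes with the next smallest p, named after their values were seen, were Snord73b at 0.89 ± 0.15, Snord35a at 1.08 ± 0.19, Snord82 at 0.48 ± 0.09, Lman2l at -0.34 ± 0.06 and Snord47 at 1.19 ± 0.22 (limma, adjusted p = 0.304 for each). Without the pool at CT12, or without that at CT36, 18 genes passed. With phase as a factor these are the same fit, since a pool left alone in its phase holds no difference between cycles. No list passed a test after adjustment, except with the preset correlation of camera. The mean of 15 immature sensory neuron genes differed between the cycles by -0.15 ± 0.07 (SD, 6 pairs of pools), and that of 11 mature neuron genes by -0.13 ± 0.07. Odorant transduction genes differed by -0.09 ± 0.06 and markers of the sustentacular supporting cells by -0.05 ± 0.02. In each of these 4 lists, and in the clock modifiers at -0.11 ± 0.07, the second cycle read lower in 6 of 6 pairs, for which an exact sign-flip test gives p = 0.03125, the smallest it can give with 6 pairs, and 0.244 after adjustment over 39 lists. Camera called 10 lists with a preset correlation and 0 with an estimated one. The adjusted p with an estimated correlation was 0.804 for both neuron lists and 0.895 for transduction and the sustentacular markers. Along with these lower neuron lists, the second cycle read higher in 49 of 51 small nucleolar RNA genes, by a mean of 0.49 ± 0.40 (SD, 6 pairs) and in 6 of 6 pairs. This group was chosen from its values, so its exact sign-flip p of 0.03125 and its p of 0.031 in camera with an estimated correlation are not independent evidence, and 0 of its genes passed in limma. Odorant receptors read higher in 644 of 1015 cases by a list mean of 0.04, and vomeronasal receptors in 127 of 165 by 0.04 (adjusted p = 0.895 and 0.804 with an estimated correlation). The first of these was 0.010 without the pair CT32 and CT56 and 0.071 without the pair CT12 and CT36, and the second 0.024 without the latter pair. For the receptor lists, scaling that depends on level was not tested. Ribosomal protein genes differed by 0.05, oxidative phosphorylation by 0.04, secretory genes of the respiratory lining by 0.13 and axon guidance genes by -0.11 (adjusted p = 0.804, 0.895, 0.884 and 0.884 with an estimated correlation). Without the pair CT12 and CT36 the respiratory value was 0.079 and that of oxidative phosphorylation 0.057, and without the pair CT28 and CT52 the latter was 0.020.

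**Figure D3:**
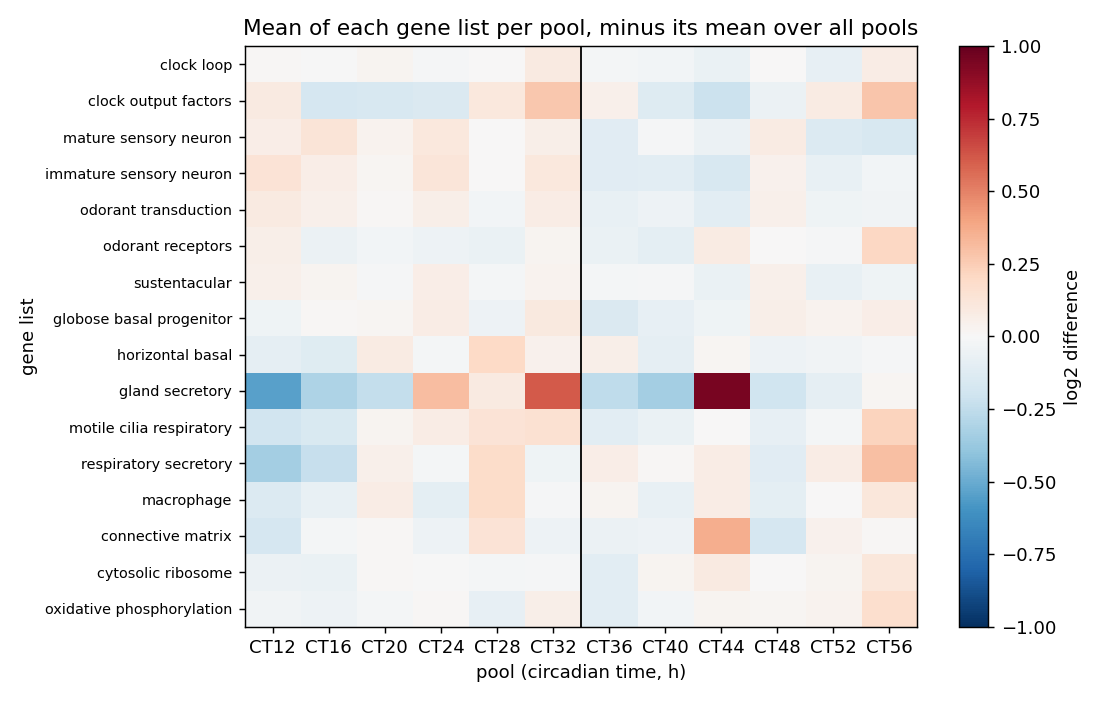
Mean of 16 gene lists (vertical axis) in each of the 12 pools (horizontal axis, circadian time in h), as the log2 difference from the mean of the list over all pools. The line parts both cycles. Gland genes reach 0.95 in the CT44 pool, while the neuron lists differ between the cycles by -0.13 and -0.15.

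A 12 h rhythm, added to the 24 h terms, was sought in the same way. No gene passed in limma, and 1063 had an unadjusted p under 0.05, against 997 by chance. The smallest p belonged to Atp6v0d2, a subunit of the vacuolar proton pump, with an adjusted p of 0.685 in limma. A change of the 24 h rhythm between the first and the second cycle was also tested. No gene passed in limma, 143 had an unadjusted p under 0.05, and the smallest adjusted p was 0.9999. On simulated data of this size, the cosines of both cycles were set opposed to each other, with an amplitude of their difference of 0.3, 0.5 or 1. Of these, 1.5%, 19.4% and 87.9% were found, so that small changes of the rhythm were not detectable here. A gain or loss of amplitude at a fixed phase was not simulated.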

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

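The tests weighed in this part were all chosen after the values had been seen. The means of the 39 lists were screened for a pool far from the other pools within the 6 pools of each side of the night and day and of the cycle comparison. In 156 such groups, 12 flags arose where chance gives about 7.8. The ratio of the gap to the range exceeded Dixon's 95% value for 6 samples in 5 pools. The CT44 pool had high gland genes among the night pools (0.792) and among the second cycle pools (0.721), high connective matrix genes (0.665) and low trace amine receptors (0.647), both among the night pools. The CT56 pool had high odorant receptors (0.651) and ribosomal protein genes (0.645) among the day pools and high motile cilia genes (0.675) in the second cycle. The CT52 pool had low heat shock genes (0.697) and low xenobiotic metabolism genes (0.677) among the day pools. The CT28 pool had high horizontal basal cell markers (0.633) and endothelial markers (0.648) among the day pools, and the CT32 pool high cholesterol synthesis genes (0.628) in the first cycle.

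The gland genes of the CT44 pool belong to a wider pattern. The mean of 14 genes of the nasal glands ranged over 1.49 log2 units across the 12 pools. Bpifb9b, which encodes a secreted protein of the lipid-binding family, read 5.93 at CT12 and 13.12 at CT44, and the odorant-binding protein gene Obp1a 8.62 at CT48 and 13.49 at CT44. Time of day as the whole reason is argued against, because 0.519 of the variance of the list mean lay between pools of the same phase. A constant shift of whole arrays is argued against too, since the medians of the 12 columns lie between 7.81 and 7.92. With medians so close, centring could change little, and the SD over pools after it was 1.022 times that before it. Scaling that depends on level was not tested. Differing amounts of gland tissue in the dissected pools may contribute, as the mean correlation between the gland genes was above that of 95.81% of lists matched on level, but at 0.111 it was low, so the genes did not move as 1 block.

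Xist, the RNA that silences an X chromosome in female cells, read 9.67 on its 1 probe in the CT24 pool and between 5.72 and 6.23 in the 11 other pools, although the labels give male mice throughout. A wholly female pool is argued against, because the mean of 3 Y-linked genes (Eif2s3y, Uty and Kdm5d) differed from the 11 other pools by -0.03837. The SD between those pools was 0.159. In the CT24 pool 0 probes other than Xist stood out by as wide a gap. This cannot decide on a defect of the array, since the median of the other pools was also 0 and the highest 2. For 1 female among the 4 mice the Y-linked genes go against it. With readings in proportion to the RNA, an equal share would give a difference of -0.415 log2 units, or -2.61 SD of the other pools. The difference found was -0.2412 SD, and 4 of the 11 other pools lay lower. That explanation stays open because the expected value is assumed. The X-linked genes Kdm6a, Eif2s3x, Kdm5c and Ddx3x, which escape the silencing, read higher by 0.19, 0.21, 0.08 and 0.32. The SDs between the other pools were 0.23, 0.10, 0.17 and 0.26. However, the CT48 pool of the same phase, with Xist at 5.995, read close to the CT24 pool in these genes. The values were 9.59, 11.13, 9.51 and 11.57 at CT48, and 9.62, 11.19, 9.48 and 11.56 at CT24. The higher X-linked values thus cannot be set apart from the phase of the pool. No biological explanation was tested.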

How the results depend on the processing

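The residual component, the fit without CT32 and CT56 and the tests with random orders, splits and swaps were chosen after the data were seen. In 4 of 100 random orders of the pools, the real one included, the 24 h fit called 5 genes or more. That share lies under 0.05, but 100 orders are too few to tell it from 0.05. Chance as the source of the 5 calls is therefore not firmly excluded. Among the other orders, 1 called 3226 genes, which points to variation shared between pools. Of 100 splits into 2 groups of 6, 14 gave as many genes at an unadjusted p under 0.05 as night against day (1965, highest other 6560), and 31 gave 10 lists or more (highest other 16). Of 32 swaps within phases, 3 reached the 2625 genes of the cycle comparison (highest other 4430), 13 its 10 lists (highest other 14) and 18 the 143 genes of the interaction (highest other 1374). Of 100 orders, 38 reached the 1063 genes of the 12 h fit (highest other 5715). Chance could not be excluded for any of these.

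The number of 24 h genes was within 1.5 times of 5 in 17 of 28 alternatives. It was 0 with a period of 22 h, 2 with 26 h, 0 by rank test, 17 with phase as a factor, of which 4 were among the 5, 8 with 12 h terms and 11 with the residual component, and all 5 were among those of the last pair of fits. Without CT32 and CT56 it was 4, of which 3 were among the 5. Without single pools it lay between 3 and 5. Dbp, Nr1d1 and Cd44 were called without each single pool, with adjusted p in limma up to 0.0149, 0.0149 and 0.0202, while Arntl was called in 7 and Rnase1 in 3 of 12 such fits. The phases of the fitted cosines were compared at the middle of the time course, on a 24 h scale. Those of the 5 genes moved by at most 0.4 h and those of 50 other named genes by at most 5.74 h. The rank test, phase as a factor, the trended prior and leaving out dim genes do not alter the cosine, so they could not move it. Nor could the cycle block, the 12 h terms or the residual component, which do not overlap with the 24 h terms in this balanced design. Rhythmic genes peaking in the day numbered 0 with a period of 22 h and 5 with array weights, and 2 to 3 without single pools. Night against day gave 2 genes with the 0 and 12 h phases left out, and 0 in the other 22 alternatives. The cycle comparison gave 1 gene without the genes below the 25th percentile, 1 with the trended prior and 17 with array weights, and 0 to 18 without single pools. The 12 h test gave 68 genes with array weights and 0 otherwise. The interaction gave 0 in 20 of 20, and the list rhythm 1 list in 18 of 18. Lists called by camera with the preset correlation for night against day numbered 4 without the genes below the 50th percentile and 7 to 13 without single pools, and for the cycles 6 to 12 without single pools. With an estimated correlation 0 lists were called in each. Both neuron lists, transduction and the sustentacular markers stayed below 0 in 18 of 18 alternatives. For the fits without pools this outcome was fixed in advance, since each of these lists read lower in 6 of 6 pairs. Only the alternatives in normalization, dim genes and probes could have turned out otherwise. The fit with a cycle block called 4 genes, all among the 5, and lost Rnase1 (adjusted p = 0.0575 in limma). The causes of these moves were not tested.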

Other observations

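The tests with random orders and with the neuron covariate were chosen after the values had been seen. Some genes that did not pass over all genes had large fitted amplitudes. Rasgrp4, an activator of Ras, had an amplitude of 0.66 ± 0.11 with a peak at CT 21.2 (adjusted p = 0.283 in limma), and the linker histone gene H1f2 one of 0.54 ± 0.09 with a peak at CT 3.1 (adjusted p = 0.139 in limma). Adgrf1, an adhesion receptor, had an amplitude of 0.37 ± 0.05 with a peak at CT 20.6 (adjusted p = 0.104 in limma), and Fmo5, a monooxygenase, one of 0.26 ± 0.04 with a peak at CT 9.8 (adjusted p = 0.125 in limma). These 4 were named after their values were seen.

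Genes that guide or sort the axons of sensory neurons had fitted peaks at different times of day. Kirrel2 and Epha5 had peaks at CT 19.9 and CT 20.7, and Kirrel3 and Efna5 at CT 11.6 and CT 9.1; all but Kirrel2 were named after their values were seen. In all, 5 of the 11 members had an unadjusted p under 0.05 in limma, but 3 without the pool at CT12, 3 with median centring, 3 with a period of 26 h and 1 in the rank test. A changing share of mature neurons was weighed as the source of that count. With the mean of 10 mature neuron markers as a covariate, 6 members had an unadjusted p under 0.05. The mean of all 11 mature neuron genes had a 24 h amplitude of 0.05 ± 0.04, so the covariate could remove little of a 24 h signal. Plxna1 joined the count as the SE of its amplitude fell from 0.058 to 0.038. The markers thus showed little 24 h change in that share, and the count of 6 adds nothing to this. A chance order of the pools stays open, because with an unmoderated F test, used for 100000 random orders, 4 members had a p under 0.05, and the permutation p of that count was 0.00727 for this list alone but 0.1418 after adjustment over the 39 lists.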
